A study of Mus musculus with 9 samples.

How the data were processed

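RNA was profiled in regulatory T cells (Tregs) of mice that carry a green fluorescent reporter of Foxp3, the transcription factor that defines this lineage. The animals were 8 weeks old, and cells were taken 3 days after ischemia/reperfusion injury of the heart, in which blood flow is blocked and then restored. Per the labels' protocols, cells of the injured heart, the spleen and the mediastinal lymph node (MLN), which drains the heart, were sorted first on magnetic beads and then by flow cytometry into lysis buffer. Libraries were made with a SMARTer kit for very small RNA amounts, which amplifies cDNA by PCR before sequencing. Each organ has 3 libraries, 9 in all. The labels do not say whether the libraries of an organ came from separate animals or pools, so the p-values measure only the spread between these samples, part of which may be technical.

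The authors deposited 1 table of raw read counts per gene for the 9 libraries, not normalized and not pooled. The programs CASAVA 1.8.2, HISAT2 and HTSeq 0.6.0 and the mouse build mm10 are named per the submitters' processing notes. The aligner's version and settings, the strand option and the annotation release are not given in the sources used here. Reads of overlapping genes, of genes with an antisense partner and of near-identical copies, such as immunoglobulin segments, histocompatibility genes and clustered gene models, are therefore uncertain. All 9 columns of counts were used, and 0 columns of values were left out. The table has 49510 genes, and 84 symbols are shared by more than 1 gene. Of the gene identifiers, 49412 were found in the GENCODE vM21 annotation of GRCm38, the assembly that mm10 names, which gave the coordinates.

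Totals ranged from 156194012 to 267520538 counts per library, and 14562 to 18570 genes had at least 1 count. At this depth a count of 0 allows up to 3 counts per library, and this floor was used for every fold against a group with no count. Such folds are lower bounds, written as at least N-fold. Floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. The spread between libraries of 1 organ was far larger than counting error, with a median biological coefficient of variation of 102%. No pair of libraries agreed within sampling noise, so none was merged.

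Genes were tested in R 4.3.3 with edgeR 4.0.16 on the deposited counts. Genes were kept by edgeR's own filter (a minimum count of 10 and a minimum total of 15), which left 16609, and libraries were scaled by trimmed mean of M-values (TMM). One quasi-likelihood model with a term per organ was fitted to all 9 libraries, with 6 residual degrees of freedom, and each pair of organs was compared by a two-sided test. P-values were adjusted by the Benjamini-Hochberg method, and a gene was called changed below 0.05. Levels are in CPM, which divides each count by its library's scaled total so that libraries are comparable, given as mean ± SD over the 3 libraries of an organ. Fold changes are given on the log2 scale with a standard error (SE) derived from the F statistic, and no SE is given where 1 group had no count.

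Before the data were examined, 31 gene lists were fixed. The 16 function lists covered Treg identity, effector and tissue Treg, naive and recirculating T cell, co-inhibitory and costimulatory receptor, chemokine receptor and integrin, repair and growth factor, DNA replication and mitosis, type I interferon response, immediate early and dissociation response, glycolysis and hypoxia, oxidative phosphorylation, fatty acid uptake and oxidation, cholesterol biosynthesis, T helper lineage factor and cytokine, NF-kB and TNF response, and unfolded protein and heat shock response. The 13 lists of other cells covered cardiomyocyte, fibroblast and extracellular matrix, endothelial cell, pericyte and smooth muscle, macrophage and monocyte, neutrophil, dendritic cell, B cell, plasma cell, cytotoxic lymphocyte, conventional CD4 T cell and pan-T, innate lymphoid and mast cell, and erythroid and platelet. The other 2 lists, nuclear-encoded cytosolic ribosomal protein and mitochondrially encoded genes, bear on RNA quality. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the 31 lists, which compares a list with all other genes. The same test with an estimated correlation, and fry, which tests whether a list's genes move on balance in 1 direction, were alternatives. Members were also counted with p-values adjusted over all genes and adjusted over the list alone. Medians of a list take members with an empty group at their lower bound.

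The genes named in the text follow a rule that was also fixed before the data were examined. It takes, per comparison, the 6 highest and the 6 lowest genes by fold change among changed genes with non-overlapping libraries and at least 10 CPM in the higher organ, without clone or model names. It adds up to 3 called members of each function list or, where none passed, the first measured member, up to 3 most abundant members of each list of other cells, and Foxp3, Il2ra, Ctla4, Ikzf2, Il1rl1, Areg, Sparc, Ccr7 and Mki67. Not every gene of the rule is printed, and some are not reported here. The results also name members of the lists from outside the rule, such as Bgn, Postn, Timp1, Gpr83 and Cd3e, which were chosen after their values were seen.

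The procedure was tested on simulated counts for the 16609 genes, in which 50 genes were changed at each fold. The changed genes were picked only from genes above a minimum mean level, so the shares recovered do not cover the genes with the lowest levels. Each gene was drawn on its own, with its mean over all 9 libraries, the real library sizes and edgeR's estimate of its spread. For heart versus spleen, edgeR recovered 0% of genes changed 4-fold, 12% at 16-fold, 32% at 64-fold and 42% at the highest fold simulated. For heart versus MLN it recovered 0% at 4-fold, 12% at 16-fold, 30% at 64-fold and 48% at the highest fold, and in both comparisons it called 0 unchanged genes. In the same simulation 74.7% of DESeq2's 466 calls for heart versus spleen and 74% of its 481 calls for heart versus MLN were unchanged genes. For limma-voom with sample quality weights these shares were 6.45% of 31 calls and 8.57% of 35 calls. A simulation of MLN versus spleen with no changed gene gave 0 calls with edgeR.

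Alternatives to the scaling, the filter on low counts, the samples in the fit, a replicate block, the tool (DESeq2 1.42.0 and limma-voom with sample quality weights), a minimum fold change, the list test and each library in turn were planned before the data were examined. Settings that take out or model the 3 libraries with the highest scaling factors were added afterwards. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.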

Results

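Gene expression was measured by RNA sequencing in Tregs of the injured heart, the spleen and the MLN, with 3 libraries from each organ, 3 days after ischemia/reperfusion injury. The comparisons of the heart with the spleen and with the MLN ask how Tregs of the injured muscle differ from Tregs of lymphoid organs. The comparison of the MLN with the spleen gives the difference between the lymphoid organs alone. Total counts of libraries 1, 2 and 3 were 156194012, 209283548 and 233749879 for the spleen, 213834915, 220511499 and 221872020 for the MLN, and 238048249, 226279297 and 267520538 for the heart. The first principal component of log CPM held 35% of the variance and placed the heart libraries between 258 and 281 and the lymphoid libraries between -159 and -88. Within each organ 1 library stood apart: spleen 3, MLN 3 and heart 2 had the highest scaling factors (1.24, 1.17 and 1.11) and the lowest shares of B2m, the light chain of class I histocompatibility molecules (1.2%, 1.55% and 1.25% of counts). Many list members named below as called lie outside the rule for named genes and were chosen after their values were seen.

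In heart Treg libraries, gene lists of fibroblasts, cardiac muscle, vessels and myeloid cells were higher than in spleen Treg libraries, lists of B cells and plasma cells were lower, and so was Ikzf2, which encodes the Treg transcription factor Helios. Ikzf2 (ENSMUSG00000025997, chromosome 1, 69531214 to 69687245, mm10) fell from 1446 ± 329 CPM in the spleen to 291 ± 60.4 CPM in the heart (SD, n = 3 each), a 4.97-fold difference (log2 -2.31, SE 0.41, adjusted p = 0.0492, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). That call held in 5 of 18 alternatives, among them 1 of the 9 that left out 1 library. Cd44 (ENSMUSG00000005087, chromosome 2, 102811141 to 102901665), a hyaluronan receptor of antigen-experienced T cells that myeloid and stromal cells also carry, rose 6.31-fold, from 236.9 ± 76.5 to 1495 ± 518 CPM (adjusted p = 0.0452, same test). Dcn (ENSMUSG00000019929, chromosome 10, 97479609 to 97518143), the collagen-binding proteoglycan decorin of fibroblasts, rose from 0.183 ± 0.0499 to 7422 ± 7729 CPM (log2 15.3, SE 1.32, edgeR adjusted p = 0.0238). Ighm (ENSMUSG00000076617, chromosome 12, 113418558 to 113422730), the heavy chain of IgM made by B cells, fell 41.9-fold, from 3273 ± 609.6 to 78.1 ± 41.4 CPM (edgeR adjusted p = 0.0238).

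Of 16609 genes tested against the spleen, 131 changed by the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, 102 higher and 29 lower in the heart, and 2264 had an unadjusted p below 0.05. In 89 of the 131 genes 1 organ had no count in any library: 68 had none in the spleen and 21 none in the heart. Levels of the organs did not overlap for 3204 genes (19.3%, where chance gives 10%). Genes with no count in 1 organ had the highest fitted folds, whose order depends on the prior count, so only their lower bounds are given. Among abundant ones were Fstl1, a secreted glycoprotein of stromal cells, at least 27350-fold higher at 399.6 ± 412.7 CPM in the heart against no count in the spleen, and Ccl8, a monocyte-attracting chemokine, at least 22640-fold higher at 330.6 ± 281 CPM (edgeR adjusted p = 0.0444 and 0.0379). Further such genes were the adhesion molecule Cadm2 (at least 21800-fold), the matrix protein Smoc2 (at least 18190-fold), the basement membrane collagen Col4a2 (at least 14770-fold) and the transporter Abca8a (at least 12190-fold). Among the lowest were the B cell kinase Blk (53.8 ± 31.5 CPM in the spleen, at least 3806-fold lower in the heart), Oosp1 (at least 2107-fold), the secretory granule chaperone Scg5 (at least 1929-fold), Prg2 (at least 1121-fold) and the antibody segment Igkv6-23 (at least 716.6-fold).

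Lists of non-blood cells of the heart were higher in the heart libraries, and all 4 stayed called with an estimated correlation. The fibroblast list rose in 8 of 25 members over all genes and in 22 adjusted over the list alone, with a median log2 change of 11.31 (camera adjusted p = 1.34e-37, adjusted p = 0.0124 with an estimated correlation). Its members Bgn, Mgp, Postn and Col5a1 encode matrix proteins and were among the 8, and its counts made up 1.11 ± 0.757% of heart libraries and 0.00441 ± 0.00322% of spleen libraries. The cardiomyocyte list rose in 3 of 17 members over all genes, Myl2, Mb and Fabp3, and in 8 adjusted over the list alone, while the sarcomere titin gene Ttn was lower. The median was 6.97 (camera adjusted p = 1.2e-10 and adjusted p = 0.0124 with an estimated correlation). Mb, the oxygen store myoglobin of muscle, was at 172.2 ± 151.8 CPM in the heart and had no count in the spleen (at least 11790-fold higher, edgeR adjusted p = 0.0398). Of the endothelial list, 0 of 20 members passed over all genes and 10 rose adjusted over the list alone. The list's median was 7.06 (camera adjusted p = 4.24e-12 and adjusted p = 0.0143 with an estimated correlation). In the pericyte and smooth muscle list, Rgs5, a pericyte regulator of G protein signalling, was at 88.6 ± 56.4 CPM against no count (at least 6068-fold). It was 1 of 10 members that rose over all genes, against 6 adjusted over the list alone. The median change was 8.67 (camera adjusted p = 8.65e-09 and adjusted p = 0.0191 with an estimated correlation).

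The macrophage and monocyte list rose in 4 of 30 members over all genes, Cd68, Ccl2, Ccr2 and Fcgr3, and in 20 adjusted over the list alone (median 2.73, camera adjusted p = 4.71e-19, adjusted p = 0.0124 with an estimated correlation), at 3.75 ± 1.2% of heart and 1.09 ± 0.0979% of spleen counts. Lyz2, the macrophage lysozyme, was at 5166 ± 2184 CPM in the heart and 953.8 ± 417.4 CPM in the spleen (log2 2.44, SE 0.59, edgeR adjusted p = 0.0958). None of 15 neutrophil genes passed over all genes and 9 rose adjusted over the list alone. The list had a median of 5.93 (camera adjusted p = 1.47e-07 and adjusted p = 0.0201 with an estimated correlation). The innate lymphoid and mast cell list showed 0 of 15 over all genes and 10 adjusted over the list alone (median 7.80, camera adjusted p = 5.74e-07, adjusted p = 0.046 with an estimated correlation), and its mast cell carboxypeptidase Cpa3 was at 6444, 3553 and 0 CPM in heart libraries 1, 2 and 3. The dendritic cell list was higher with 0 of 19 members called by either adjustment. Its share of counts was not higher, at 0.937 ± 0.483% in the heart and 1.18 ± 0.342% in the spleen. The listed genes had a median of 1.08 (camera adjusted p = 0.0177, adjusted p = 0.366 with an estimated correlation, 0.0536 without spleen 1, 0.193 without heart 2, 0.129 with a stricter filter and 0.0699 with both organs fitted alone). B cell genes fell in 3 of 19 members over all genes, Blk and Ighm among them, and in 16 adjusted over the list alone. The median log2 change was -7.18 (camera adjusted p = 1.51e-29 and adjusted p = 0.0151 with an estimated correlation). Plasma cell genes fell in 3 of 14, the antibody genes Ighg2b, Iglv1 and Iglc2, and in 6 adjusted over the list alone. The median over members was -6.81 (camera adjusted p = 1.36e-11 and adjusted p = 0.0191 with an estimated correlation). Counts of the B cell list made up 1.21 ± 0.354% of spleen and 0.0162 ± 0.00314% of heart libraries. Whether these antibody and B cell counts came from B cells in the spleen libraries or from Tregs was not tested.

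**Figure D1:**
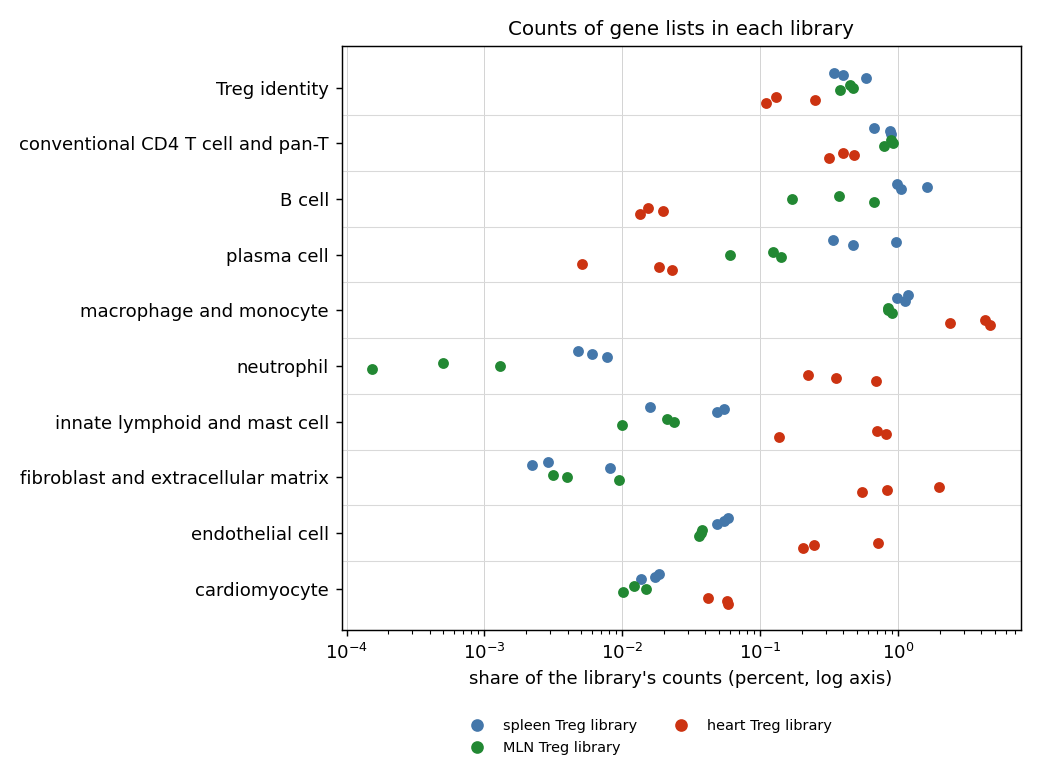
Share of each library's counts (percent, log axis) that 10 gene lists took, with 1 point per library and 3 libraries each for spleen, MLN and heart Tregs. Fibroblast genes averaged 1.11% in heart libraries against 0.00441% in spleen and 0.0055% in MLN libraries, and B cell genes averaged 0.0162% in heart against 1.21% in spleen and 0.404% in MLN libraries.

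The Treg identity list was lower in the heart than in the spleen, with 1 of 19 members, Ikzf2, called over all genes and 4 adjusted over the list alone, Ikzf2, Gpr83, Izumo1r and Nt5e. Members had a median change of -0.74 (camera adjusted p = 0.00014 and adjusted p = 0.105 with an estimated correlation). The Treg identity list took 0.163 ± 0.0749% of heart and 0.441 ± 0.124% of spleen counts, while the pan-T list, with T cell receptor and coreceptor genes, took 0.398 ± 0.0812% and 0.807 ± 0.123%. The pan-T list was lower too, with 0 of 20 members called over all genes and 1, Cd3e, adjusted over the list alone. The list's members had a median of -1.02 (camera adjusted p = 0.00317 and adjusted p = 0.194 with an estimated correlation). Foxp3 (ENSMUSG00000039521, chromosome X, 7573644 to 7595245) was at 15.7 ± 19.8 CPM in the heart and 83.7 ± 89.7 CPM in the spleen (edgeR adjusted p = 0.546), with 0.24 CPM in heart 3 and 187 CPM in spleen 3. The IL-2 receptor chain Il2ra was at 198.8 ± 59.1 against 348.9 ± 91.9 CPM (adjusted p = 0.357, edgeR) and the inhibitory receptor Ctla4 at 410.1 ± 125.6 against 704.9 ± 197.6 CPM (adjusted p = 0.383, edgeR).

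The effector and tissue Treg list was higher, with 1 of 26 members, Cd44, called over all genes and 7 adjusted over the list alone. Its median change was 0.55 (camera adjusted p = 0.0104, adjusted p = 0.376 with an estimated correlation, 0.078 without spleen 1, 0.0852 without heart 2 and 0.0616 with limma-voom). The other 6 were Gzmb, Icos, Il1rl1, Rora, Rbpj and Fgl2, and Rora is also in the innate lymphoid and mast cell list. Il1rl1, the IL-33 receptor of tissue Tregs that mast cells also carry and that is in the mast cell list too, was at 47.3 ± 7.02 CPM in the heart and 6.63 ± 2.67 CPM in the spleen (log2 2.83, SE 0.56, edgeR adjusted p = 0.0651). Areg, a growth factor of tissue Tregs, was at 155.7 ± 66.3 and 138.3 ± 102 CPM (edgeR adjusted p = 0.992). The naive and recirculating T cell list was lower (median -0.80, camera adjusted p = 0.00405, adjusted p = 0.353 with an estimated correlation), yet its 1 member of 19 called over all genes, the transcription regulator Id3, rose 12.3-fold (edgeR adjusted p = 0.0374). Adjusted over the list alone, Id3 was higher and 3 members were lower, among them Lef1 and Bcl2, a transcription factor and a survival factor of resting T cells. The chemokine receptor Ccr7, which guides T cells to lymph nodes, was at 217.4 ± 232 CPM in the heart and 1154 ± 286 CPM in the spleen (edgeR adjusted p = 0.209). The co-inhibitory and costimulatory receptor list was lower with 0 of 20 members over all genes and 2, Cd96 and Cd27, adjusted over the list alone. The median was -0.48 (camera adjusted p = 0.0336, adjusted p = 0.353 with an estimated correlation, 0.0948 without spleen 2 and 0.09 with both organs fitted alone).

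The repair and growth factor list was higher, with 0 of 29 members over all genes and 13 adjusted over the list alone. The list's median was 2.55 (camera adjusted p = 2.62e-08 and adjusted p = 0.0264 with an estimated correlation). The 13 included the protease inhibitors Timp1 and Timp2, the growth factors Igf1 and Hbegf and the matrix protein Sparc, which is also in the fibroblast list, whose share of counts was 1.11 ± 0.757% in the same libraries. Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183) was at 995.6 ± 360.9 CPM in the heart and 2.3 ± 3.8 CPM in the spleen (log2 8.76, SE 2.11, edgeR adjusted p = 0.118). Fatty acid uptake and oxidation genes were higher, with 0 of 25 over all genes and 5 adjusted over the list alone (median 0.78, camera adjusted p = 0.00405, adjusted p = 0.046 with an estimated correlation), of which Cd36 and Fabp4 are also in the endothelial list. Glycolysis and hypoxia genes were higher, with 1 of 28 over all genes, the hexokinase Hk2 (8.02-fold, edgeR adjusted p = 0.0398), and 2 adjusted over the list alone, Hk2 and Bnip3. The median change was 0.82 (camera adjusted p = 0.00405, adjusted p = 0.261 with an estimated correlation and 0.0519 without heart 2). By share of counts the list lay at 0.198, 0.535 and 0.254% in heart 1, 2 and 3 and at 0.201, 0.162 and 0.408% in spleen 1, 2 and 3. These ranges overlapped, and the highest value of each organ was in a library that stood apart.

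The NF-kB and TNF response list was higher in the heart than in the spleen, with 1 of 25 members over all genes, the chemokine Ccl4 (74.6-fold, from 36.5 ± 34.1 to 2718 ± 1708 CPM, edgeR adjusted p = 0.0492), and 4 adjusted over the list alone. Ccl4 was called in 5 of 18 alternatives and in 0 of the 9 that left out 1 library, with log2 changes from 5.775 to 7.339 over the alternatives. The list had a median of 0.76 (camera adjusted p = 0.00405, adjusted p = 0.363 with an estimated correlation and 0.128 without heart 2), in libraries where the macrophage list took 3.75 ± 1.2% of counts. T helper factors and cytokines were higher, with 0 of 26 over all genes and 6 adjusted over the list alone, Csf2, Ahr, Tnf, Il6, Rora and Il5. The listed genes had a median of 1.03 (camera adjusted p = 0.00628, adjusted p = 0.261 with an estimated correlation and 0.0559 without heart 2). Rora and Il5 are also in the innate lymphoid and mast cell list, which took 0.551 ± 0.364% of heart and 0.0396 ± 0.0208% of spleen counts. The immediate early and dissociation response list was higher, with 1 of 30 over all genes, the heat shock gene Hspa1b, and 5 adjusted over the list alone. The median log2 change was 0.80 (camera adjusted p = 0.00317, adjusted p = 0.376 with an estimated correlation and 0.126 without heart 2). The list's share of counts was 0.957% in heart 2, 0.461% and 0.446% in the other heart libraries, and 0.814% in spleen 3. Hspa1b itself was low, at 7.549, 8.081 and 1.873 CPM in heart 1, 2 and 3 against no count in the spleen. Its call held in 3 of 17 alternatives and in 0 of the 9 that left out 1 library. Interferon response genes were higher, with 0 of 26 over all genes and 1, Ifit2, adjusted over the list alone. Their share of counts was not higher, at 0.194 ± 0.012% in the heart and 0.207 ± 0.114% in the spleen. The median over members was 0.45 (camera adjusted p = 0.0336 and adjusted p = 0.537 with an estimated correlation). That call ended without spleen 2 (0.746), spleen 3 (0.0924), MLN 1 (0.0579), MLN 2 (0.061), heart 2 (0.0559) or heart 3 (0.0999), and with both organs fitted alone (0.106). The unfolded protein and heat shock list was lower with 0 of 23 members called by either adjustment. Members had a median change of -0.51 (camera adjusted p = 0.0104, adjusted p = 0.402 with an estimated correlation and 0.149 without spleen 3). Nuclear-encoded ribosomal protein genes, a list that bears on RNA quality, were lower with 0 of 85 called by either adjustment. The list's members had a median of -0.41 (camera adjusted p = 0.00014, adjusted p = 0.604 with an estimated correlation, 0.11 without spleen 1 and 0.323 without heart 2).

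The other lists did not pass in the heart against the spleen. Their camera adjusted p-values were 0.423 for chemokine receptors and integrins, of which Ccr2 rose 6.49-fold (edgeR adjusted p = 0.0398) and is also in the macrophage list, and 0.435 for DNA replication and for mitochondrially encoded genes. They were 0.118 for cytotoxic lymphocytes and 0.0947 for erythroid cells and platelets. With a stricter filter the cytotoxic list was called higher (camera adjusted p = 0.0492). Adjusted over the list alone, Ccr2, Itgb1, the cytotoxic lymphocyte receptor Klra8 and the platelet chemokine Pf4 were higher, and the globin genes Hbb-bs, Hba-a1 and Hbb-bt were lower. Oxidative phosphorylation (0.511) had a median of 0.25 and a mean of 0.04 with a downward test, and cholesterol biosynthesis (0.435) a median of 0.06 and a mean of -0.01 with a downward test.

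Calls of single genes against the spleen depended on single spleen and heart libraries: 0 genes were called without spleen 1, spleen 2 or heart 3, 1 without spleen 3, 2 without heart 2 and 10 without heart 1, against 84, 90 and 122 without MLN 1, 2 and 3. In these fits the filter was run again and left 17636 to 18312 genes, and with the 16609 genes kept a version chosen after these counts were seen, they were 0, 0, 0, 1, 2, 10, 107, 111 and 182 in the same order. Without heart 1 most of the few genes still called were lower in both versions, with 1 higher and 9 lower (10% higher, against 77.9%), and 4 of the 10 were among the 131. This was a change in which genes were called, and no named gene reversed its direction. The count was 308 with a stricter filter on low counts, 292 (92.8% higher) with both organs fitted alone, 1148 with limma-voom and 2410 with DESeq2, and it was 3 without the libraries that stood apart and 59 (64.4% higher) with that difference as a covariate. For the genes that opened this comparison, log2 changes over 18 alternatives ran from -2.486 to -2.15 for Ikzf2 and from 2.382 to 2.958 for Cd44. They ran from 13.983 to 15.971 for Dcn and from -5.9 to -5.112 for Ighm. Their calls were less stable. Cd44 was called in 6 of 18 alternatives and in 1 of the 9 that left out 1 library. Dcn and Ighm were each called in 12 of the 18 and in 5 of those 9. Hk2, Ccr2 and Col4a2 were called in 6, 5 and 6 of 18 and in 0 of those 9. Without the libraries that stood apart, the effector Treg (camera adjusted p = 0.203), interferon (0.0973), T helper (0.0514), unfolded protein (0.131) and dendritic cell (0.0691) lists were no longer called.

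In heart Treg libraries, fibroblast, muscle, vessel, myeloid and repair lists were also higher than in MLN Treg libraries, B cell genes were lower, and Ikzf2 fell. Ikzf2 was at 291 ± 60.4 CPM in the heart and 1676 ± 642.3 CPM in the MLN (SD, n = 3 each), 5.76-fold lower (log2 -2.53, SE 0.41, edgeR adjusted p = 0.0344). That call held in 9 of 18 alternatives, among them 2 of the 9 that left out 1 library. Cd44 rose 11.6-fold, from 128.9 ± 46.4 to 1495 ± 518 CPM (edgeR adjusted p = 0.0204), and Il1rl1 (ENSMUSG00000026069, chromosome 1, 40429570 to 40465415) rose 9.88-fold, from 4.79 ± 1.72 to 47.3 ± 7.02 CPM (edgeR adjusted p = 0.0388). Lyz2 (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321) rose 12.4-fold, from 416.6 ± 213.7 to 5166 ± 2184 CPM (edgeR adjusted p = 0.0383).

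Against the MLN 230 genes changed by the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment, 183 higher and 47 lower in the heart, and 2581 had an unadjusted p below 0.05. In 127 of the 230 genes 1 organ had no count: 101 had none in the MLN and 26 none in the heart. Levels did not overlap for 4345 genes (26.2%, where chance gives 10%). The highest fitted fold was that of Sparc, with no count in the MLN and 1242, 1163 and 581 CPM in heart libraries 1, 2 and 3 (at least 75600-fold, edgeR adjusted p = 0.0454, and between 9.5e-05 and 0.172 over its alternatives). Among the next were Fstl1 (at least 30340-fold), the Sparc relative Sparcl1 (at least 28750-fold), the endothelial sialoprotein Emcn (at least 26400-fold), Cadm2 (at least 24180-fold) and Smoc2 (at least 20170-fold). Among the lowest were the antibody gene Ighg2b (100.6 ± 54.3 CPM in the MLN, at least 7123-fold lower in the heart), Scg5 (at least 4611-fold), Igkv6-23 (at least 2907-fold), Blk (at least 2479-fold) and Fsd2 (at least 821.1-fold).

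The fibroblast list rose against the MLN in 8 of 25 members over all genes and in 21 adjusted over the list alone. Its median change was 11.17 (camera adjusted p = 2.45e-31 and adjusted p = 0.0176 with an estimated correlation). Among the matrix genes Dcn rose from 3.23 ± 1.69 to 7422 ± 7729 CPM (log2 11.17, SE 1.16, edgeR adjusted p = 0.0152). Cardiomyocyte genes rose in 3 of 17, again Myl2, Mb and Fabp3, and in 10 adjusted over the list alone. The median was 7.98 (camera adjusted p = 4.9e-11 and adjusted p = 0.0115 with an estimated correlation). Endothelial genes rose in 3 of 20, Cd36, Emcn and Fabp4, and in 13 adjusted over the list alone. The list's median was 7.79 (camera adjusted p = 9.04e-13 and adjusted p = 0.0176 with an estimated correlation). In the pericyte list Rgs5 rose over all genes, and 5 of 10 members adjusted over the list alone. The median change was 6.12 (camera adjusted p = 1.29e-06 and adjusted p = 0.0334 with an estimated correlation). The macrophage list rose in 10 of 30 members, among them the complement genes C1qa and C1qb, the lipopolysaccharide co-receptor Cd14 and Lyz2, and in 26 adjusted over the list alone. The list had a median of 5 (camera adjusted p = 4.74e-31 and adjusted p = 0.0115 with an estimated correlation). Neutrophil genes rose in 3 of 15, Lcn2, Il1b and Trem1, and in 13 adjusted over the list alone. The listed genes had a median of 8.49 (camera adjusted p = 9.89e-14 and adjusted p = 0.0176 with an estimated correlation). Il1b, the cytokine IL-1 beta, was at 1625 ± 655.8 CPM in the heart and 0.591 CPM in the MLN.

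Mast cell and innate lymphoid genes rose in 3 of 15, the mast cell chymase Cma1, Il1rl1 and the neuropeptide Calca, and in 7 adjusted over the list alone. The median log2 change was 6.35 (camera adjusted p = 5.55e-07 and adjusted p = 0.0566 with an estimated correlation). The dendritic cell list was higher with 0 of 19 called by either adjustment. The median over members was 0.84 (camera adjusted p = 0.0465 and adjusted p = 0.4 with an estimated correlation). That call ended without MLN 1 (0.0735), MLN 2 (0.16), heart 2 (0.321) or heart 3 (0.0744), with another scaling of the libraries (0.0521) and with a stricter filter (0.148). B cell genes fell in 3 of 19 over all genes and 16 adjusted over the list alone. Members had a median change of -6.64 (camera adjusted p = 1.77e-22 and adjusted p = 0.0334 with an estimated correlation). Ighm fell 7.08-fold, from 553 ± 103.4 to 78.1 ± 41.4 CPM (edgeR adjusted p = 0.0319). The B cell list took 0.404 ± 0.251% of MLN counts, and whether these came from B cells in the MLN libraries was not tested. Plasma cell genes fell in 3 of 14 and in 5 adjusted over the list alone. The list's members had a median of -1.50 (camera adjusted p = 6.66e-06 and adjusted p = 0.0728 with an estimated correlation).

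**Figure D2:**
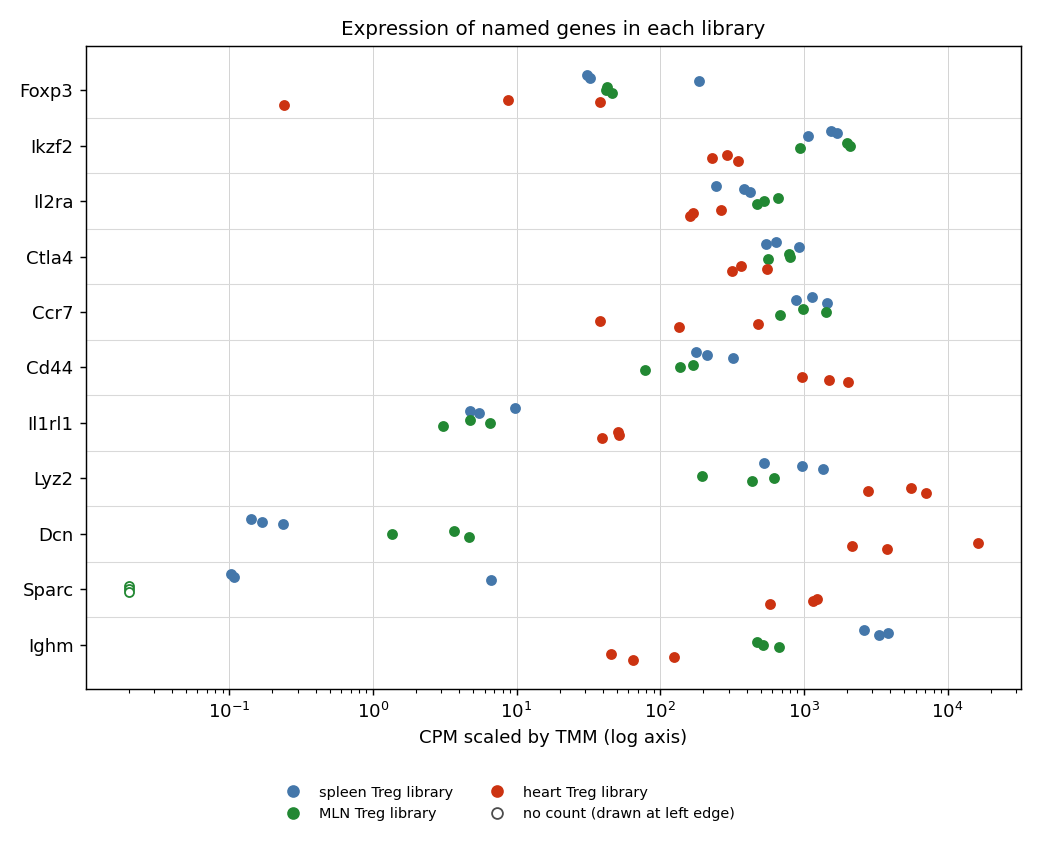
Level of 11 named genes (CPM scaled by TMM, log axis), with 1 point per library, 3 libraries per organ, and open points at the left edge for libraries with no count. Ikzf2 lay between 229 and 350.1 CPM in heart libraries and between 936 and 2093 CPM in spleen and MLN libraries, whereas Foxp3 in heart 1, 2 and 3 was at 8.77, 38 and 0.24 CPM.

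The Treg identity list was lower against the MLN, with 2 of 19 members called over all genes, Ikzf2 and the folate receptor family gene Izumo1r (7.42-fold lower, edgeR adjusted p = 0.0419), and 6 adjusted over the list alone. Its median change was -0.81 (camera adjusted p = 0.000458 and adjusted p = 0.157 with an estimated correlation). The 6 were Ikzf2, Il2ra, Gpr83, Izumo1r and Nt5e, all lower, and the ectonucleotidase Entpd1, which was higher. Pan-T genes were lower in the same libraries, with 0 of 20 called over all genes and 3, Slamf6, Trbc1 and Trbc2, adjusted over the list alone. The median was -0.72 (camera adjusted p = 0.0103 and adjusted p = 0.268 with an estimated correlation). Foxp3 was at 15.7 ± 19.8 CPM in the heart and 43.5 ± 2.45 CPM in the MLN (edgeR adjusted p = 0.735), Ctla4 at 410.1 ± 125.6 and 718.4 ± 133.3 CPM (edgeR adjusted p = 0.319), and Ccr7 at 217.4 ± 232 and 1031 ± 371 CPM (edgeR adjusted p = 0.219). Effector and tissue Treg genes were higher, with Cd44 and Il1rl1 called over all 16609 genes and 6 of 26 adjusted over the list alone, Cd44, Il10, Il1rl1, Rora, Rbpj and Fgl2. The list's median was 1.10 (camera adjusted p = 0.000385 and adjusted p = 0.242 with an estimated correlation). The naive list was lower, with 1 of 19 members called over all genes and 2 adjusted over the list alone, Bcl2 among them. The median change was -0.51 (camera adjusted p = 0.00211 and adjusted p = 0.276 with an estimated correlation). The co-inhibitory and costimulatory receptor list was lower with 0 of 20 over all genes and 2, Cd96 and Cd27, adjusted over the list alone. The list had a median of -0.10 (camera adjusted p = 0.0394 and adjusted p = 0.316 with an estimated correlation). That call ended without MLN 1 (0.125), MLN 2 (0.0674), heart 1 (0.0526) or heart 3 (0.059), with a stricter filter (0.0548), with both organs fitted alone (0.0504), and with another scaling, under which the median was 0.01 (0.0521).

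The repair and growth factor list rose against the MLN in 1 of 29 members over all genes, Sparc, and in 15 adjusted over the list alone (median 3.95, camera adjusted p = 1.47e-10, adjusted p = 0.0176 with an estimated correlation), in libraries where fibroblast genes took 1.11 ± 0.757% of counts. Fatty acid genes rose in 2 of 25, Cd36 (88.3-fold, edgeR adjusted p = 0.0283) and Fabp4, both also in the endothelial list, and in 7 adjusted over the list alone. The listed genes had a median of 0.57 (camera adjusted p = 0.00337 and adjusted p = 0.047 with an estimated correlation). Glycolysis genes rose in 1 of 28, Hk2 (6.24-fold, edgeR adjusted p = 0.0419), and in 3 adjusted over the list alone, Hk2, Hif1a and Bhlhe40. The median log2 change was 1.32 (camera adjusted p = 0.00201 and adjusted p = 0.243 with an estimated correlation). The list's share of counts was 0.198, 0.535 and 0.254% in heart 1, 2 and 3 against 0.269, 0.253 and 0.2% in MLN 1, 2 and 3, so by share only heart 2, 1 of the libraries that stood apart, lay above all 3 MLN libraries, although the list stayed called without heart 2 (camera adjusted p = 0.00942). The immediate early list was higher, with Egr1, a transcription factor induced within minutes of stimulation, called over all genes (10.3-fold, edgeR adjusted p = 0.0479) and 7 of 30 adjusted over the list alone. The median over members was 1.69 (camera adjusted p = 3.28e-05 and adjusted p = 0.276 with an estimated correlation). NF-kB and TNF response genes were higher with 0 of 25 over all genes and, adjusted over the list alone, 9 higher and 1 lower. Members had a median change of 1.47 (camera adjusted p = 3.28e-05 and adjusted p = 0.242 with an estimated correlation). The 9 included the chemokines Ccl3 and Ccl4 and the feedback inhibitors Tnfaip3 and Nfkbia, and the lower gene was the cytokine Ltb. In the same libraries the macrophage list took 3.75 ± 1.2% of heart and 0.861 ± 0.0285% of MLN counts. T helper factors and cytokines were higher with 0 of 26 over all genes and 3, Tnf, Rora and Il5, adjusted over the list alone. The list's members had a median of 1.32 (camera adjusted p = 0.0133, adjusted p = 0.276 with an estimated correlation and 0.105 without MLN 3). Rora and Il5 are also in the innate lymphoid and mast cell list, which took 0.551 ± 0.364% of heart and 0.0182 ± 0.00728% of MLN counts.

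Ribosomal protein genes were lower in the heart than in the MLN with 0 of 85 called by either adjustment (median -0.80, camera adjusted p = 9.7e-12, adjusted p = 0.4 with an estimated correlation), at 3.22 ± 0.883% of heart and 7.03 ± 0.154% of MLN counts. The lists that did not pass had camera adjusted p-values of 0.304 for chemokine receptors and integrins, 0.117 for DNA replication, 0.361 for the interferon response, 0.966 for the unfolded protein response, 0.892 for mitochondrially encoded genes, 0.0772 for cytotoxic lymphocytes and 0.851 for erythroid cells and platelets. DNA replication was called lower with limma-voom (camera adjusted p = 0.0172) and with no filter on low counts (0.0484). Cytotoxic lymphocytes were called higher with no filter (camera adjusted p = 0.0434) and with the libraries that stood apart as a covariate (0.0379). Among chemokine receptors and integrins, Ccr2 rose 7.15-fold (edgeR adjusted p = 0.0308) and the integrin Itgb1 rose 3.47-fold, from 123.1 ± 2.08 to 427.5 ± 48.6 CPM (edgeR adjusted p = 0.0429), and Itgav joined them adjusted over the list alone. Of the cytotoxic list, Klra8 rose over all genes, and Cd8b1, a chain of the CD8 coreceptor, was lower adjusted over the list alone. Oxidative phosphorylation (0.198) had a median of 0.08 and a mean of -0.03 with a downward test, and cholesterol biosynthesis (0.684) a median of -0.11 and a mean of 0.20 with a downward test.

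With the filter run again, 0 genes were called against the MLN without MLN 1 or heart 3, and the count was 36 without MLN 3, 39 without MLN 2, 24 without heart 1 and 59 without heart 2. Without heart 1 there were 11 higher and 13 lower (45.8% higher, against 79.6%), and 16 of the 24 were among the 230. With the 16609 genes kept, 9 genes were called without MLN 1, 45 without MLN 2 or MLN 3, 41 without heart 1 (48.8% higher), 57 without heart 2 and 0 without heart 3. It was 381 with a stricter filter on low counts, 548 with both organs fitted alone, 1747 with limma-voom, 2781 with DESeq2 and 4 without the libraries that stood apart. Without those libraries the effector Treg (camera adjusted p = 0.0932), T helper (0.199) and dendritic cell (0.102) lists were no longer called, and the DNA replication list was called lower (0.0027). Over 18 alternatives, Cd44 was called in 12, Il1rl1 in 9, Lyz2 in 8 and Egr1 in 6. In the 9 that left out 1 library, these genes were called in 5, 3, 2 and 0.

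Against both lymphoid organs, 89 genes were higher and 29 lower in the heart, and 0 were called in opposite directions. The 89 included the matrix and stromal genes Dcn, Fstl1 and Smoc2, the myeloid receptor Fcgr3, Cd44, Ccr2 and Hk2, and the 29 included Ikzf2, Ighm, Blk and Scg5. Independent calls would share 1.12 higher and 0.0821 lower genes, a value that leaves out that both comparisons use the same heart libraries. At an unadjusted p below 0.05, 985 higher and 566 lower genes were shared, against means of 41.8 and 183.6 in 20 simulated designs with no changed gene and the heart libraries in common. Simulated genes varied independently, unlike the real ones, so these means may be too low. In drawn regroupings of the real libraries that broke up the heart group, the highest were 218 higher genes (spleen 2, spleen 3 and heart 2 as the heart) and 450 lower genes (spleen 1, MLN 1 and MLN 2 as the heart). Il1rl1, Cd36 and Lyz2, called against the MLN and not against the spleen, are not shown to differ between those comparisons, since the difference was not tested. The shared higher genes numbered 0 without spleen 1, spleen 2, MLN 1 or heart 3, 1 without spleen 3, heart 1 or heart 2, 16 without MLN 2 and 17 without MLN 3. The shared lower genes numbered 0 without spleen 1, spleen 2, spleen 3, MLN 1 or heart 3, 1 without heart 2, 8 without heart 1, 10 without MLN 2 and 12 without MLN 3.

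**Figure D3:**
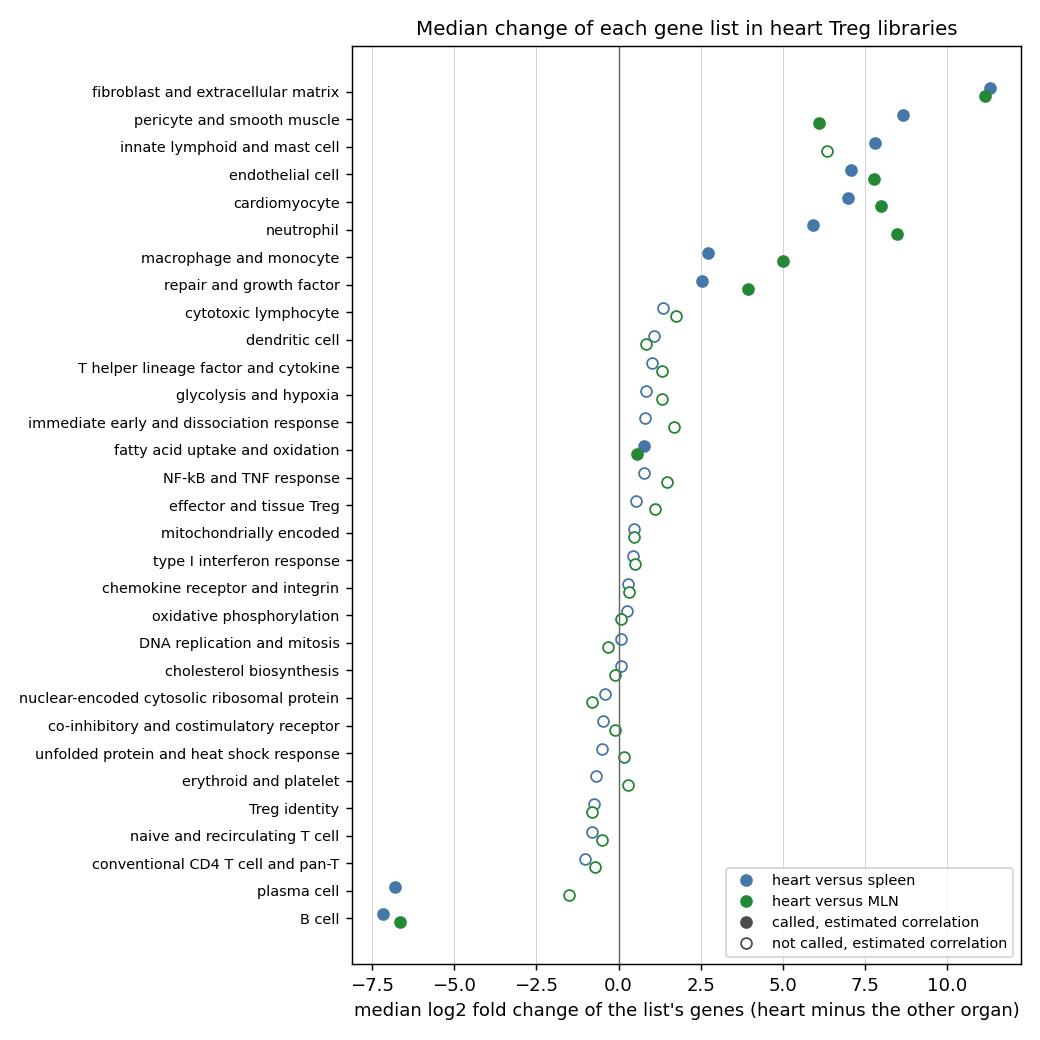
Median log2 fold change of the genes of each of 31 lists (heart minus the other organ), with 1 point for the spleen and 1 for the MLN, genes with no count in 1 organ at their lower bound, and filled points for lists called with an estimated correlation. The fibroblast list lay highest (11.31 and 11.17) and the B cell list lowest (-7.18 and -6.64), while Treg identity lay at -0.74 and -0.81 and was not called with an estimated correlation.

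Between the MLN and the spleen, macrophage and neutrophil genes were lower in the MLN as lists, and no single gene was called. Both list calls were lost with an estimated correlation (adjusted p = 0.0868 for both), with which 0 lists were called. The edgeR quasi-likelihood test called 0 of 16609 genes after Benjamini-Hochberg adjustment (smallest adjusted p = 0.11), 955 had an unadjusted p below 0.05, and levels did not overlap for 1508 (9.08%, where chance gives 10%), while DESeq2 called 868 and limma-voom 30. Ighm was at 553 ± 103.4 CPM in the MLN and 3273 ± 609.6 CPM in the spleen (SD, n = 3 each, log2 -2.57, SE 0.44, edgeR adjusted p = 0.427). Ikzf2 was at 1676 ± 642.3 and 1446 ± 329 CPM and Foxp3 at 43.5 ± 2.45 and 83.7 ± 89.7 CPM (edgeR adjusted p = 1 for both).

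The macrophage list was lower in the MLN, with 0 of 30 members over all genes and, adjusted over the list alone, 5 lower and 1 higher. Its median change was -1.22 (camera adjusted p = 3.46e-11 and adjusted p = 0.0868 with an estimated correlation). Its lysozyme Lyz2 was at 416.6 ± 213.7 CPM in the MLN and 953.8 ± 417.4 CPM in the spleen (edgeR adjusted p = 0.839). Neutrophil genes were lower with 0 of 15 over all genes and 3, Lcn2, Il1b and Trem1, adjusted over the list alone. The median was -4.79 (camera adjusted p = 2.62e-09 and adjusted p = 0.0868 with an estimated correlation). Plasma cell genes were lower as a list (median -1.68, camera adjusted p = 0.00677, adjusted p = 0.681 with an estimated correlation, 0.0735 without spleen 2 and 0.143 with a stricter filter), although its 1 gene called adjusted over the list alone, Ighg2b, was higher. Erythroid and platelet genes were lower with 0 of 12 called by either adjustment. The list's median was -1.30 (camera adjusted p = 0.00422, adjusted p = 0.19 with an estimated correlation, 0.202 without spleen 2, 0.113 without MLN 1 and 0.079 without MLN 3). The unfolded protein list was lower (median -0.63, camera adjusted p = 0.000221, adjusted p = 0.681 with an estimated correlation and 0.087 without spleen 3), with 0 of 23 members called by either adjustment. DNA replication genes were higher (median 0.34, camera adjusted p = 0.00025, adjusted p = 0.681 with an estimated correlation and 0.0781 without spleen 3), as were ribosomal protein genes, with 0 of 34 and 0 of 85 called by either adjustment. For ribosomal protein genes the median change was 0.39 (camera adjusted p = 2.57e-07, adjusted p = 0.8 with an estimated correlation and 0.506 without spleen 3). Without the libraries that stood apart, the erythroid (camera adjusted p = 0.062) and unfolded protein (0.387) lists were no longer called and the B cell list was called lower (0.000496).

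The remaining lists did not pass between the MLN and the spleen. Camera adjusted p-values of the function lists were 0.801 for Treg identity, 0.105 for effector Treg and for repair genes, 0.525 for naive T cell, 0.832 for co-inhibitory, 0.754 for chemokine receptor and for cholesterol genes, 0.126 for interferon, 0.12 for immediate early, 0.719 for glycolysis, 0.34 for oxidative phosphorylation, 0.505 for fatty acid, 0.535 for T helper and 0.0684 for NF-kB genes. They were 0.397 for cardiomyocyte, 0.286 for fibroblast, 0.143 for endothelial, 0.363 for pericyte, 0.942 for dendritic cell, 0.086 for B cell, 0.767 for cytotoxic and for pan-T, 0.741 for mast cell and 0.477 for mitochondrially encoded genes. Median, mean and test differed in sign for co-inhibitory genes (0.08, -0.14, upward), cholesterol genes (0.04, -0.21, downward), pan-T genes (-0.02, 0.04, downward) and mast cell genes (-0.47, 0.80, downward). In these lists Hspa1b (immediate early), Dcn (fibroblast) and Socs2 (Treg identity) were higher and Ighm (B cell) lower in the MLN adjusted over the list alone, and 0 passed over all genes. Levels were low for Hspa1b (2.094, 1.085 and 0.599 CPM in MLN 1, 2 and 3) and for Dcn (3.649, 1.369 and 4.673 CPM). Limma-voom called the interferon list higher (camera adjusted p = 0.0017) and the B cell list lower (1.41e-05). The immediate early list was called lower with a stricter filter (camera adjusted p = 0.00279). With both organs fitted alone, the immediate early (camera adjusted p = 0.0271), repair (0.0354), NF-kB (0.0354) and B cell (0.00804) lists were called lower.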

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

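Alternatives that took out or modelled the 3 libraries with the highest scaling factors and those that left out 1 library with the genes of the main filter kept were chosen after seeing the data, and all others were planned. Scaling by relative log expression, no filter on low counts and a minimum absolute log2 fold change of 1 left each count of changed genes within 1.5 times its value, at 118 to 138 genes for heart versus spleen, 171 to 272 for heart versus MLN and 0 for MLN versus spleen. For the values below, in the order heart versus spleen, heart versus MLN, genes higher and genes lower in the heart than in both lymphoid organs, the cause was not tested unless the setting's construction gives it. A stricter filter, which left 10089 genes to adjust over, gave 308, 381, 213 and 46 genes. Fitting only both organs of a comparison gave 292, 548, 189 and 16 genes, and 11 lists for MLN versus spleen. DESeq2 gave 2410, 2781, 1169 and 526 genes and 868 for MLN versus spleen, and limma-voom with sample quality weights gave 1148, 1747, 899 and 112 genes and 30 for MLN versus spleen. DESeq2 gave no list results. In the simulation, which used edgeR's own estimates of spread, most of DESeq2's calls were unchanged genes. That share need not hold in the real data. Without the 3 libraries with the highest scaling factors, which leaves 6 libraries, 3, 4, 3 and 0 genes were called. With that library type as a covariate, 59 genes were called for heart versus spleen, 33 were higher than in both lymphoid organs, and 11 lists were called for MLN versus spleen.

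Leaving out each library in turn, which leaves 1 degree of freedom less and ran the filter again (17636 to 18312 genes), gave 0 to 122 genes for heart versus spleen, 0 to 249 for heart versus MLN, 0 for MLN versus spleen, 0 to 17 higher and 0 to 12 lower than in both lymphoid organs, and 17 to 24, 20 to 23 and 4 to 14 lists for heart versus spleen, heart versus MLN and MLN versus spleen. With the 16609 genes of the main filter kept, the counts without spleen 1, 2 and 3, MLN 1, 2 and 3 and heart 1, 2 and 3 were 0, 0, 1, 107, 111, 182, 10, 2 and 0 for heart versus spleen, 230, 232, 301, 9, 45, 45, 41, 57 and 0 for heart versus MLN and 0 throughout for MLN versus spleen. They were 0, 0, 1, 1, 20, 22, 1, 1 and 0 for genes higher and 0, 0, 0, 2, 11, 14, 8, 1 and 0 for genes lower than in both lymphoid organs. The mitochondrially encoded list, not called in heart versus MLN with all libraries, reversed to lower without heart 3 (median -0.13, camera adjusted p = 0.0261, with medians from -0.13 to 0.73 over the libraries left out), and the cause was not tested. With an estimated correlation 11, 9 and 0 lists were called in the comparisons of heart with spleen, heart with MLN and MLN with spleen, and fry called 13, 17 and 0. Among results for single named genes under the alternatives chosen beforehand, 421 lost a call, 74 gained 1 and 2732 did neither, and among those for single lists 102 lost a call, 40 gained 1, 1437 did neither and 1 reversed. The alternatives on the 3 libraries ended 79 calls of named genes and 10 of lists and gave 1 and 7. Of 2570 values of uncalled named genes under alternatives, 109 had the other sign.

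The libraries share only replicate numbers: correlations between same-numbered libraries of different organs ranged from -0.127 to 0.114 over 9 pairs, and 1 of 9 libraries correlated best with its own number. With the replicate number as a block, 0 genes were called in heart versus spleen and in heart versus MLN, and 0 were higher or lower than in both lymphoid organs. The block left 24, 21 and 9 lists called: it ended the call of the co-inhibitory and costimulatory receptor list in heart versus MLN (0.0632) and added the B cell list and the NF-kB and TNF response list in MLN versus spleen (0.0327 for both). Depth was not varied in any alternative.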

Other observations

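The tests of stromal, myeloid and T cell genes given here were chosen only after the result was seen, and the counts of other splits of the libraries were planned before. The genes named here were called in both comparisons of the heart, lie outside the gene lists and were chosen after their values were seen, so they stand as single genes and no shared function was tested. The filament protein Vim was at 486.8 ± 62 CPM in the heart, 92.2 CPM in the spleen and 103.2 CPM in the MLN (edgeR adjusted p = 0.0238 and 0.0193). Litaf, which regulates TNF expression in macrophages, was at 3858 ± 656.5 CPM against 528.9 and 262.9 CPM, and Plek, a kinase substrate of platelets and leukocytes, at 2278 ± 160.4 CPM against 117.4 and 108.8 CPM, in libraries where the macrophage list took 3.75% of counts, against 1.09% and 0.861%. The cell cycle inhibitor Cdkn1a was at 278 CPM against 16.4 and 18.8 CPM. Lower in the heart were Rhoh, a GTPase of T cell receptor signalling (64.8 CPM against 280 and 379.9 CPM), the tetraspanin Tspan32 (12.6 CPM against 91.5 and 110 CPM) and Rabgap1l (102.4 CPM against 535.8 and 450.5 CPM).

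A segment of chromosome 14 (3049285 to 7994573, mm10), also chosen after its values were seen, held many genes without counts in the heart. Of its 53 tested genes 26 (49.1%) had no count in any heart library, against 483 (2.91%) of all tested genes, and 4 of the genes lower than in both lymphoid organs lay there, Gm3739, Gm3696, Gm10406 and Gm3500. The shares are not matched for level. Some of the 26 were very low in the lymphoid libraries too, such as Gm9602 (0 to 0.07 CPM), and others higher, such as Gm3739 (11.05 to 46.38 CPM). These gene models are near copies of one another, so how reads were divided among them is uncertain, and a difference of strain or pool between the libraries was not examined.

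Fibroblast, muscle, vessel and pericyte genes higher in the heart may come from RNA of other heart cells, which the sort on magnetic beads and by Foxp3 reporter was meant to remove. Foxp3 itself was at 8.77, 38 and 0.24 CPM in heart 1, 2 and 3, and the share of Tregs among the sorted cells is not given in the sources used here. After the same sort, B cell genes took 1.21 ± 0.354% of spleen and 0.404 ± 0.251% of MLN counts, so removal of other cells' RNA cannot be assumed. All 4 lists of non-blood heart cells were higher in both comparisons with an estimated correlation, which expression by heart Tregs would give too, with Dcn at 7422 CPM, Cd36 at 3176 CPM and Gsn at 1393 CPM in the heart. Of the list members tested, 2 of 25 fibroblast, 5 of 17 cardiomyocyte, 3 of 20 endothelial and 0 of 10 pericyte genes reached 10 CPM in the lymphoid libraries, and 1, 0, 3 and 0 are in another list. Sparc, whose ratio to the summed other matrix genes varied 3.77-fold over the heart libraries, less than that of 9 of the other 21 members with at least 10 CPM, could come from that source, on a measure that was seen beforehand and decides nothing. Lower depth of the lymphoid libraries is argued against, as heart levels would give a median of 4410 counts in the smallest spleen library, and both RNA of other heart cells and expression by heart Tregs, which was not tested, stay open.

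Myeloid genes higher in the heart may come from macrophage, monocyte and neutrophil RNA in the heart libraries, which the same sort was meant to remove. Of the macrophage list's 30 members, 24 were higher in every heart library than in every lymphoid library, but this restates the list's call and would follow from expression by heart Tregs as well. Its genes Ctss and Lyz2 were at 15500 and 5166 CPM in the heart. Of the 30, 20 also reached 10 CPM in the lymphoid libraries and 4 are in another list, and of 15 neutrophil genes 1 reached that level there and 2 are in another list. Both sources stay open, and expression by heart Tregs was not tested.

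Lower Treg and naive T cell genes in the heart may reflect a lower share of T cell RNA in the heart libraries. Against both lymphoid organs, 12 pan-T genes, a subset of the list chosen after its values were seen, had a median log2 change of -0.88 and the 19 Treg identity genes one of -0.56, a difference of -0.317 (two-sided permutation test over genes, which are not independent replicates, p = 0.451), but members of both lists went both ways, so the medians do not decide. The pan-T genes ranged from -1.30 for Trbc2 to 0.54 for Cd4, and 6 of the 19 Treg identity genes lay below Trbc2, among them Gpr83 (-4.02), Izumo1r (-2.82) and Ikzf2 (-2.42). For Ccr7, Ikzf2 and Lef1, 2 of 3 fell by more than the lowest pan-T gene (log2 changes of -2.33 for Ccr7 and -2.42 for Ikzf2, against -1.15 for Lef1). The whole pan-T list took 0.4, 0.478 and 0.316% of counts in heart 1, 2 and 3, less than in any lymphoid library (0.665 to 0.908%). Counts of T cell genes were thus lower in the heart libraries. How far a lower share of T cell RNA accounts for the fall in Treg and naive genes stays open. So does a difference between Tregs of heart and lymphoid organs, which was not tested.

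The 10 splits of the 6 libraries of each comparison are too few for a share under 0.05. In heart versus spleen the real split gave 131 genes and the highest other 1, with 1 split as high, and in heart versus MLN it gave 230 and the highest other 1, again with 1 split as high. In MLN versus spleen it gave 0 and the highest other 1, with 10 splits as high. For lists the real split and the highest other gave 24 and 18 in heart versus spleen (1 split as high), 22 and 15 in heart versus MLN (1 split as high) and 7 and 13 in MLN versus spleen (5 splits as high). Over 100 drawn splits of all 9 libraries, 1, the real one, gave as many genes as the 89 higher and 1 as many as the 29 lower than in both other groups. Mixing heart with lymphoid libraries widens the spread within groups, so low counts in such splits were built in. The splits therefore do not exclude chance for either count. The highest others were 51 and 14, from a split that kept the heart libraries together.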
